A study of Caenorhabditis elegans with 6 samples.

How the data were processed

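Disome-seq sequences the RNA fragments protected by a pair of stacked ribosomes, which are longer than those under a single ribosome. The libraries came from whole hermaphrodite *Caenorhabditis elegans* at the last larval stage, L4. Per the labels' protocols, ribosomes were pelleted through sucrose, RNA of 50 to 80 nucleotides was taken from a gel, and libraries were built with a small-RNA kit. There were 6 libraries in 2 groups of 3, grown at 23 °C from eggs placed on plates with 500 µg/ml cycloheximide (CHX) or without it. Treated animals were collected on day 3 and untreated animals on day 2, per the labels, so that both groups were L4.

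The authors deposited a table of raw read counts per gene, with 1 column per library and 20189 rows, each a protein-coding gene with its region given as the coding sequence, per the file headers. Transcript headers in that table name the WBcel235 build and give a chromosome, start and end, which are printed here as the span of the transcript named there. WBcel235 and DESeq2 are also named per the submitters' processing notes. The aligner, the counting tool, read trimming, the treatment of reads with several matches, strand and molecular identifiers are not given in the sources used here. Counts of near-identical copies (major sperm protein, histone, actin, yolk and small heat shock genes) are therefore uncertain, as are those of genes that overlap on opposite strands. Sequence names of 20079 genes matched a RefSeq table of the same build, which supplied current gene names where the file's symbol was older. All 6 library columns were mapped to samples by name. Total counts per library ranged from 1601009 to 1901815, and 3208 genes had no count in any library. A count of 0 in 1 library allows up to 3 counts, or 1.58 to 1.87 CPM (counts scaled to library size), counting error only.

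Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter with a minimum count of 10, and the quasi-likelihood test without a replicate block. Of all genes, 10632 passed the filter. Adjusted p values are Benjamini-Hochberg over those genes, with 0.05 as the threshold. Levels are TMM-normalised CPM, given as mean ± SD with n = 3. Fold changes are log2 of CHX-treated over untreated, and each standard error (SE) is the size of the log2 fold change divided by the square root of the test's F value. The same test was checked on 5 simulated data sets of 10632 genes, each with 200 genes changed by known amounts. In these simulations it called 1.60% of genes changed 1.25-fold, 27.6% at 1.5-fold, 70.8% at 2-fold and 94.8% at 4-fold. It also called 30 of 51076 unchanged genes. Gene lists were checked on 5 separate draws of counts, in which only the cytosolic ribosomal protein list was lowered and no other gene was changed. That list was called in 5 of 5 draws. Other lists, with the ribosome quality control list left out, were called in 0 of 145 tests. Genes were drawn independently, and these draws do not show how lists behave when many genes change.

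Before the data were examined, 31 gene lists were fixed by gene symbol: cytosolic and mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ribosome biogenesis, ribosome quality control, proteasome, cytochrome P450 enzymes, UDP-glucuronosyltransferases, glutathione S-transferases, P-glycoprotein and MRP transporters, surveillance and infection response genes, C-type lectins, cytosolic heat shock proteins, ER chaperones and unfolded protein response, mitochondrial chaperones and proteases, the nuclear-encoded respiratory chain, mitochondrially encoded genes, glycolysis, fatty acid synthesis and oxidation, amino acid synthesis and one-carbon enzymes, collagens, molting cycle genes, sperm genes, oocyte and early embryo genes, yolk proteins, histones, muscle, neuronal genes, intestinal genes and tubulins. Lists were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 31 lists, and again with an estimated correlation and with fry. List medians were also ranked among 10000 random lists matched gene by gene on mean count. Counts of members past the gene test are given over all genes tested and adjusted over the list alone. Some patterns took members of another function (WD-repeat genes of the wdr group and muscarinic receptors gar-1, gar-2 and gar-3 in ribosome biogenesis, the intermediate filament gene ifb-1 in translation factors), and trimmed versions were added after seeing the data. A list of germline genes outside gametes and a list of adult-onset genes (col-19 and the 6 yolk genes) were used in the closing part only.

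The rule for named genes was also fixed beforehand. It took the 8 largest rises and 8 largest falls with adjusted p under 0.05, a mean of at least 50 counts and groups that did not overlap. It added, for each list past the threshold, the 3 members with the smallest adjusted p in its direction and the 1 with the smallest against it, and up to 2 members of other lists. The 5 genes with the highest CPM in each group and 16 genes of prior interest completed it: rpl-36.A, irg-1, zip-2, hsp-4, hsp-6, hsp-16.2, xbp-1, znf-598, gcn-1, rack-1, eef-2, eef-1A.1, unc-54, daf-16, skn-1 and atf-4. Genes named outside this rule are marked as chosen after their values were seen. Shares of counts were compared with a two-sided exact permutation test, which cannot go below p = 0.10 with 3 libraries against 3.

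Alternatives were DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors in edgeR, no count filter, a filter of 50 counts in 3 libraries, the replicate number as a block, and leaving out each library in turn. A relation of fold change to coding length was planned but not run, because the length column of the table equals the genomic span of each transcript in 20179 rows and is empty in 10, and coding lengths were not in the reference used here. Figures were drawn with matplotlib 3.10.9. Monosome and RNA-seq libraries were not analysed here, so a disome count per gene moves with mRNA level, with translation and with ribosome stacking alike. The labels do not say whether replicates came from separate cultures, so p values measure the spread between these libraries, which may be technical.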

Results

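Disome footprints were counted per gene in *C. elegans* L4 hermaphrodites heterozygous for a P55Q change in rpl-36A over the chromosome II balancer mIn1. The gene, listed as rpl-36.A (WBGene00004454, WBcel235 chromosome II, 11096542 to 11097204), encodes a protein of the large ribosomal subunit that lies close to where cycloheximide (CHX), an inhibitor of elongation, binds. The study's title concerns ribosomes that resist CHX, and the comparison asks how disome counts differ between heterozygotes raised with 500 µg/ml CHX and without it. The 3 untreated libraries held 1639682, 1786600 and 1842865 counts, and the 3 CHX libraries 1740161, 1601009 and 1901815. A count was present for 14352 to 14711 genes in untreated and 14955 to 15153 in CHX libraries. Libraries of a group correlated at r = 0.970 to 0.977 across genes and libraries of different groups at 0.878 to 0.899. Within groups the chi-square per degree of freedom was 1.97 to 3.58, so that no pair looked like the same library deposited again. Treatment and day of collection (day 3 with CHX, day 2 without) changed together and cannot be separated.

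With CHX, 2367 genes rose and 2125 fell among the 10632 tested (42.2%), and 1022 rose and 513 fell by at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg). The groups did not overlap for 5577 genes (52.5%), where chance gives 10%. The median log2 fold change over tested genes was 0.03. Among genes with a mean of at least 50 counts and groups that did not overlap, the 8 largest rises included 3 oocyte genes, cpg-1 and cpg-2, which encode chondroitin proteoglycans of the eggshell, and oma-2, a zinc finger gene of oocyte maturation. Also among them were dod-24 (WBGene00007875, chromosome IV, 12940106 to 12941405), F55G11.4 (now mbug-1, WBGene00010124, chromosome IV, 12973624 to 12975591), the cytochrome P450 gene cyp-33B1, H29C22.1 and C50F7.5. F55G11.4 went from 64.4 ± 12.6 to 2047 ± 220 CPM (counts scaled to library size, mean ± SD, n = 3), a log2 fold change of 4.98 ± 0.15 (SE, adjusted p = 2.2e-10), and dod-24 from 20.6 ± 4.82 to 555 ± 20.1 CPM, a log2 fold change of 4.76 ± 0.14. Under the same limits the 8 largest falls were in the adenine nucleotide translocase genes ant-1.4 and ant-1.3, the cytochrome P450 gene cyp-35C1, the glycerol-3-phosphate dehydrogenase gene gpdh-1, the saposin-like gene spp-17, the ground-like gene grl-27, R08E5.3 (now rips-1) and E02H4.7. Of these ant-1.4 changed most, from 58.3 ± 6.03 to 8.08 ± 1.73 CPM (log2 fold change -2.84 ± 0.20, adjusted p = 3.3e-07), and the log2 fold changes of the others ran from -2.72 to -2.38. In simulations with 200 of 10632 genes changed, 27.6% of genes changed 1.5-fold were called, against 94.8% at 4-fold. Here 4492 genes passed, so the Benjamini-Hochberg cut was less strict and those rates do not carry over to this comparison. Whether depth limits the calling of small changes was not tested.

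**Figure D1:**
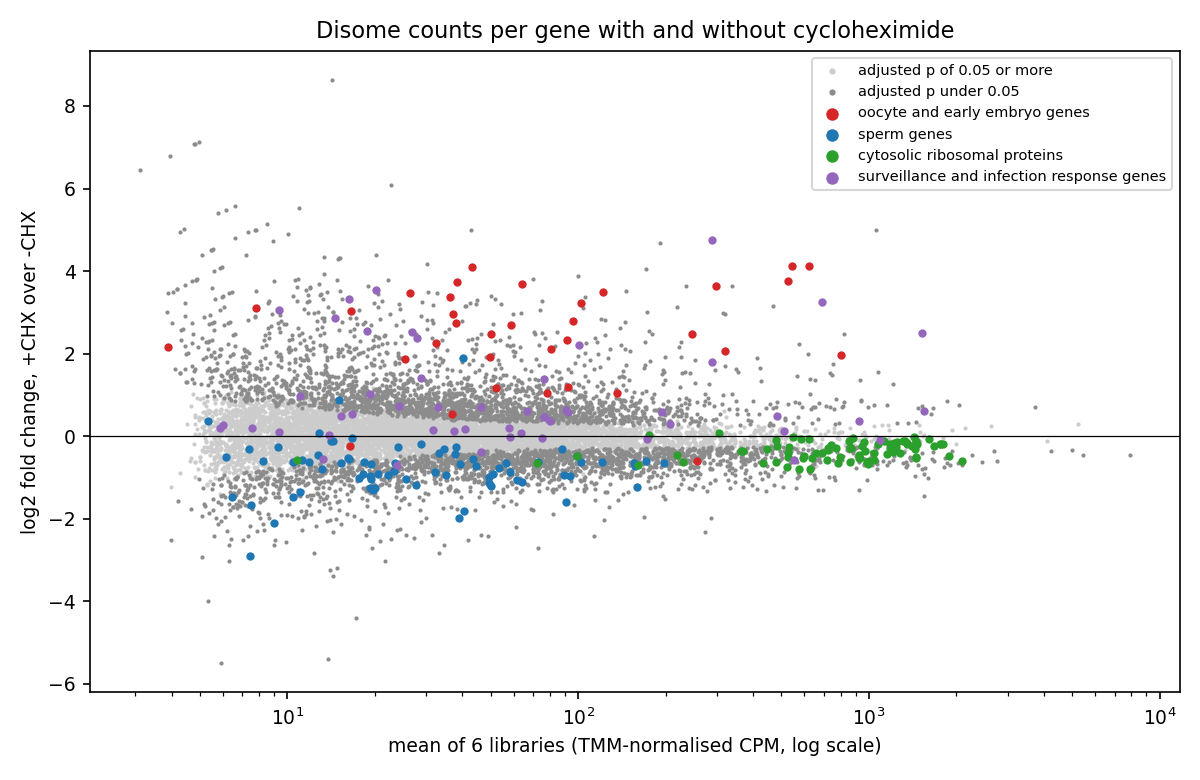
Log2 fold change of disome counts (CHX-treated over untreated, vertical axis) against mean TMM-normalised CPM of the 6 libraries (log scale) for the 10632 tested genes, dark grey where adjusted p was under 0.05, with 4 gene lists in colour. The oocyte list has a median of 2.59, the sperm list of -0.67, the surveillance list of 0.52 and the ribosomal protein list of -0.30.

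Oocyte and early embryo genes had the largest median of any list. Of 34 tested, 32 rose, 1 fell and 1 did not pass, both over all genes and adjusted over the list alone. The eggshell gene cpg-1 (WBGene00000465, chromosome III, 4489359 to 4491392) rose by 4.12 ± 0.19 on the log2 scale and the yolk receptor gene rme-2 (WBGene00004374, chromosome IV, 5469961 to 5473174) by 3.63 ± 0.15. Another eggshell gene, cpg-2, went from 59.0 ± 17.5 to 1031 ± 56.7 CPM (log2 fold change 4.13 ± 0.17). The member that fell was gld-1, which encodes an RNA-binding repressor of translation in the germline, at -0.59 ± 0.10 (edgeR adjusted p = 4.4e-04). The share of all counts in this list was 0.140% to 0.164% in untreated and 0.804% to 0.900% in CHX libraries. The list median was 2.59 (camera adjusted p = 1.3e-56; adjusted p = 0.107 with an estimated correlation).

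Sperm genes went the other way. Of 75 tested, 50 fell (53 adjusted over the list alone), 2 rose and 23 did not pass. The sperm gene spe-4 (WBGene00004958, chromosome I, 7454660 to 7456953) went from 62.3 ± 9.03 to 15.6 ± 2.51 CPM (log2 fold change -1.99 ± 0.18), F32A11.3, now spe-18, had a log2 fold change of -1.59 ± 0.17 and msrp-2 of -1.24 ± 0.13. Against the list, sss-1 rose by 1.90 ± 0.19. Among the major sperm protein genes, many of them near-identical copies whose reads cannot be assigned with certainty, 20 of 23 fell and none rose (a family chosen after its values were seen). The list's share of counts was 0.394% ± 0.0342 without and 0.245% ± 0.0340 with CHX (exact permutation p = 0.10, the smallest possible; 0.175 after Benjamini-Hochberg over 7 classes). The median of the list was -0.67 (camera adjusted p = 7.2e-11; adjusted p = 0.383 with an estimated correlation).

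**Figure D2:**
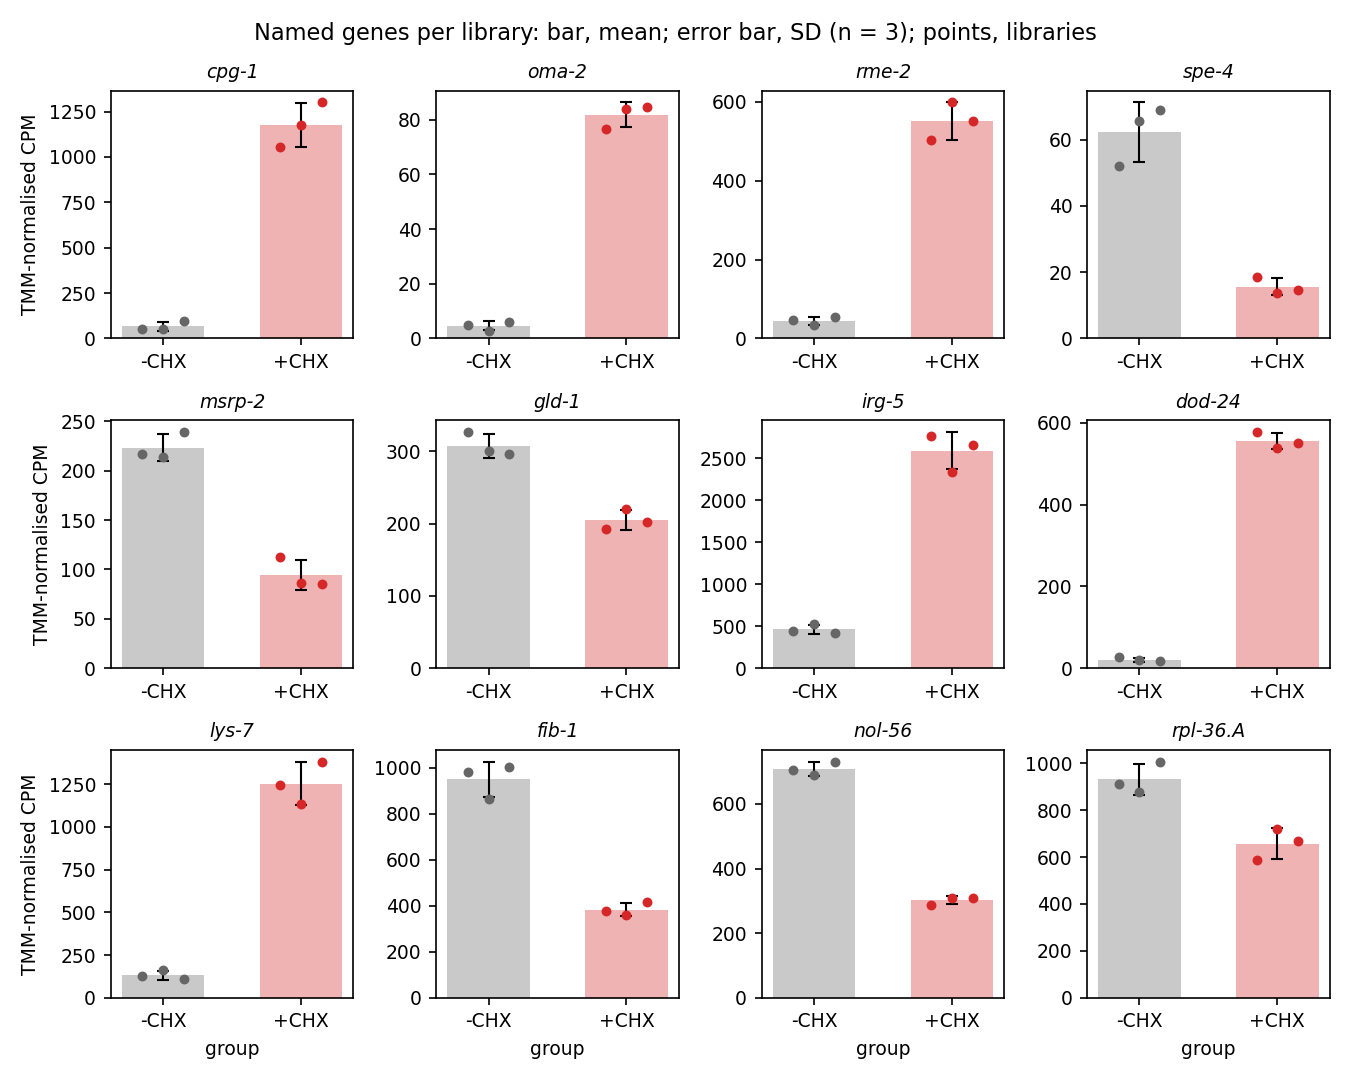
TMM-normalised CPM of 12 genes in untreated (-CHX) and CHX-treated (+CHX) libraries, with bars at the mean, error bars of 1 SD (n = 3) and a point per library. The groups do not overlap in any of the 12 panels, from cpg-1 (67.3 to 1177 CPM) to rpl-36.A (932 to 658 CPM).

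Surveillance and infection response genes rose as a group. Of 50 tested, 25 rose (26 adjusted over the list alone) and 3 fell. The infection response gene irg-5 (WBGene00009429, chromosome V, 13737007 to 13738474) went from 461 ± 56.9 to 2589 ± 223 CPM (log2 fold change 2.49 ± 0.11) and the lysozyme gene lys-7 (WBGene00003096, chromosome V, 3481421 to 3482600) from 132 ± 25.4 to 1252 ± 125 CPM (3.24 ± 0.14). A gene known to be induced when translation is blocked, irg-1, went from 15.7 ± 4.39 to 41.7 ± 4.98 CPM (1.41 ± 0.21, edgeR adjusted p = 1.7e-04), and the gene of its transcription factor, zip-2, rose by 0.58 ± 0.10. Another lysozyme gene, lys-2, fell by 0.59 ± 0.11. Over the whole list the median was 0.52 (camera adjusted p = 2.1e-10; adjusted p = 0.107 with an estimated correlation).

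C-type lectins, a large family with many members tied to pathogen responses, changed in both directions. Of 67 tested, 30 rose (31 adjusted over the list alone) and 11 fell. The gene clec-91 rose by 3.81 ± 0.20 and clec-41 by 1.98 ± 0.12, while clec-123 fell by 1.05 ± 0.15. For clec-42 there were 238 counts with CHX and 3 without, a ratio of 76.4 with a 95% exact interval of 25.8 to 373 (counting error only). The list median was 0.19 (camera adjusted p = 2.3e-04; adjusted p = 0.330 with an estimated correlation), and without a count filter the call ended (median 0.04, adjusted p = 0.055).

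Enzyme families of xenobiotic metabolism did not move as 1 block. Of 23 glutathione S-transferases, 13 fell and none rose, among them gst-10 (198 ± 2.69 to 48.5 ± 1.20 CPM, log2 fold change -2.03 ± 0.11), gst-4 (-1.36 ± 0.14) and gst-13 (-1.24 ± 0.11); the same 13 and 0 were found adjusted over the list alone. The median of the list was -0.50 (camera adjusted p = 2.3e-05; adjusted p = 0.143 with an estimated correlation). Of 34 cytochrome P450 genes 8 rose and 7 fell, over all genes and over the list alone. Among them cyp-33B1 went from 3.08 ± 2.34 to 57.5 ± 10.5 CPM and cyp-14A5 rose by 3.63 ± 0.22, while cyp-35C1 had a log2 fold change of -2.72 ± 0.28. Of 50 UDP-glucuronosyltransferases 11 rose and 22 fell (13 and 23 adjusted over the list alone), with ugt-31 at 3.87 ± 0.18 and ugt-22 at -1.99 ± 0.10. Of 21 P-glycoprotein and MRP transporters 10 rose and 4 fell, the same adjusted over the list alone, with pgp-5 at 2.37 ± 0.16 and pgp-2 at -1.06 ± 0.10. No count of pgp-7 was found without CHX and 53 with it, at least 17-fold higher against a floor of 3 counts over the group; it was chosen after its values were seen. These 3 lists did not pass camera (medians 0.15, -0.43 and 0.37; adjusted p = 0.726, 0.138 and 0.167), though without untreated replicate 1 the glucuronosyltransferases did (median -0.49, adjusted p = 0.017). The glucuronosyltransferase mean was -0.01.

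Among genes of the translation apparatus, those of cytosolic ribosomal proteins fell more often than they rose, by small amounts. Of 83 cytosolic ribosomal protein genes, 50 fell (52 adjusted over the list alone) and none rose. Examples are rpl-34 (log2 fold change -0.80 ± 0.09), rpl-25.2 (-0.79 ± 0.10) and rpl-30 (-0.75 ± 0.10). The gene of the resistance allele, rpl-36.A, went from 932 ± 66.4 to 658 ± 67.4 CPM (-0.50 ± 0.10, edgeR adjusted p = 0.0015), with reads of both alleles counted together. The class held 8.22% ± 0.381 of counts without and 6.87% ± 0.280 with CHX (exact permutation p = 0.10, the smallest possible; 0.175 after Benjamini-Hochberg). Over the whole list the median was -0.30 (camera adjusted p = 3.5e-09; adjusted p = 0.604 with an estimated correlation). That median lay at percentile 22.75 of random lists matched on mean count, whose own median was -0.25.

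Ribosome biogenesis genes also fell. Of 62 tested, 36 fell and 3 rose, over all genes and adjusted over the list alone. Fibrillarin, fib-1 (WBGene00001423, chromosome V, 15000653 to 15002273), had a log2 fold change of -1.31 ± 0.10. The nucleolin gene K07H8.10, now nucl-1, went from 1316 ± 72.5 to 529 ± 41.3 CPM and nol-56 from 708 ± 21.2 to 302 ± 12.6 CPM (log2 fold changes -1.31 ± 0.10 and -1.23 ± 0.09). Against the list, wdr-5.3 rose by 2.86 ± 0.31; it is a WD-repeat gene related to a histone methyltransferase subunit. The list median was -0.51 (camera adjusted p = 6.4e-08; adjusted p = 0.330 with an estimated correlation), and without members of other function 34 of 53 fell and 1 rose (median -0.59).

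Of 47 translation factor genes 27 fell and 4 rose (28 and 4 adjusted over the list alone). The eIF5A genes iff-1 (876 ± 94.8 to 432 ± 12.5 CPM) and iff-2 had log2 fold changes of -1.02 ± 0.10 and -0.95 ± 0.12, eif-3.C of -0.75 ± 0.10 and eef-1A.1 of -0.45 ± 0.09, while tag-260 rose by 0.76 ± 0.17. The elongation factor gene eef-2 was at -0.12 ± 0.09 (edgeR adjusted p = 0.27). The median of the list was -0.34 (camera adjusted p = 5.8e-05; adjusted p = 0.383 with an estimated correlation). Of 72 mitochondrial ribosomal protein genes 35 fell (39 adjusted over the list alone) and none rose, among them mrps-14 (-0.89 ± 0.12), mrpl-17 (-0.87 ± 0.15) and mrpl-30 (-0.82 ± 0.14), with a list median of -0.39 (camera adjusted p = 1.1e-06; adjusted p = 0.383 with an estimated correlation). Aminoacyl-tRNA synthetases had 10 of 33 lower and none higher, over all genes and the list alone, including kars-1 (-0.50 ± 0.09) and wars-1 (-0.58 ± 0.11). That list did not pass (median -0.15, camera adjusted p = 0.103), but did without a count filter (adjusted p = 0.038).

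Genes that sense or resolve ribosome collisions did not shift as a list. Of 32 tested, 6 rose and 6 fell, over all genes and the list alone (median -0.01, mean 0.07, camera direction down, adjusted p = 0.759). The nonsense-mediated decay gene smg-7 rose by 1.33 ± 0.24 and cdc-48.2 fell by 0.58 ± 0.09. Of the collision sensors named beforehand, rack-1 fell by 0.33 ± 0.10 (edgeR adjusted p = 0.015), znf-598 (listed as C52E12.1) was at -0.03 ± 0.11 (edgeR adjusted p = 0.83), and gcn-1 at -0.27 ± 0.09 (edgeR adjusted p = 0.032). Outside that set, and chosen after their values were seen, gcn-2 rose by 0.73 ± 0.16 (edgeR adjusted p = 0.0030). Lower in the same choice were abcf-2 (-0.58 ± 0.11, edgeR adjusted p = 0.0010) and abcf-1 (-0.30 ± 0.10, edgeR adjusted p = 0.028). In that choice abcf-3, skih-2, xrn-1 and pelo-1 did not pass. The gene zak-1, with a mean of 9.5 counts, was at 0.40 ± 0.36 (edgeR adjusted p = 0.41). The gcn-1 call was lost without untreated replicate 1 and without each CHX library (adjusted p = 0.062 to 0.081) and with DESeq2 (0.058). Of 33 proteasome genes 6 fell (4 adjusted over the list alone) and none rose, with rpn-6.2 at -1.07 ± 0.20 and rpt-6 at -0.42 ± 0.11. The proteasome list did not pass (median -0.06, camera adjusted p = 0.127), but did without untreated replicate 1 (median -0.18, adjusted p = 0.040).

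**Figure D3:**
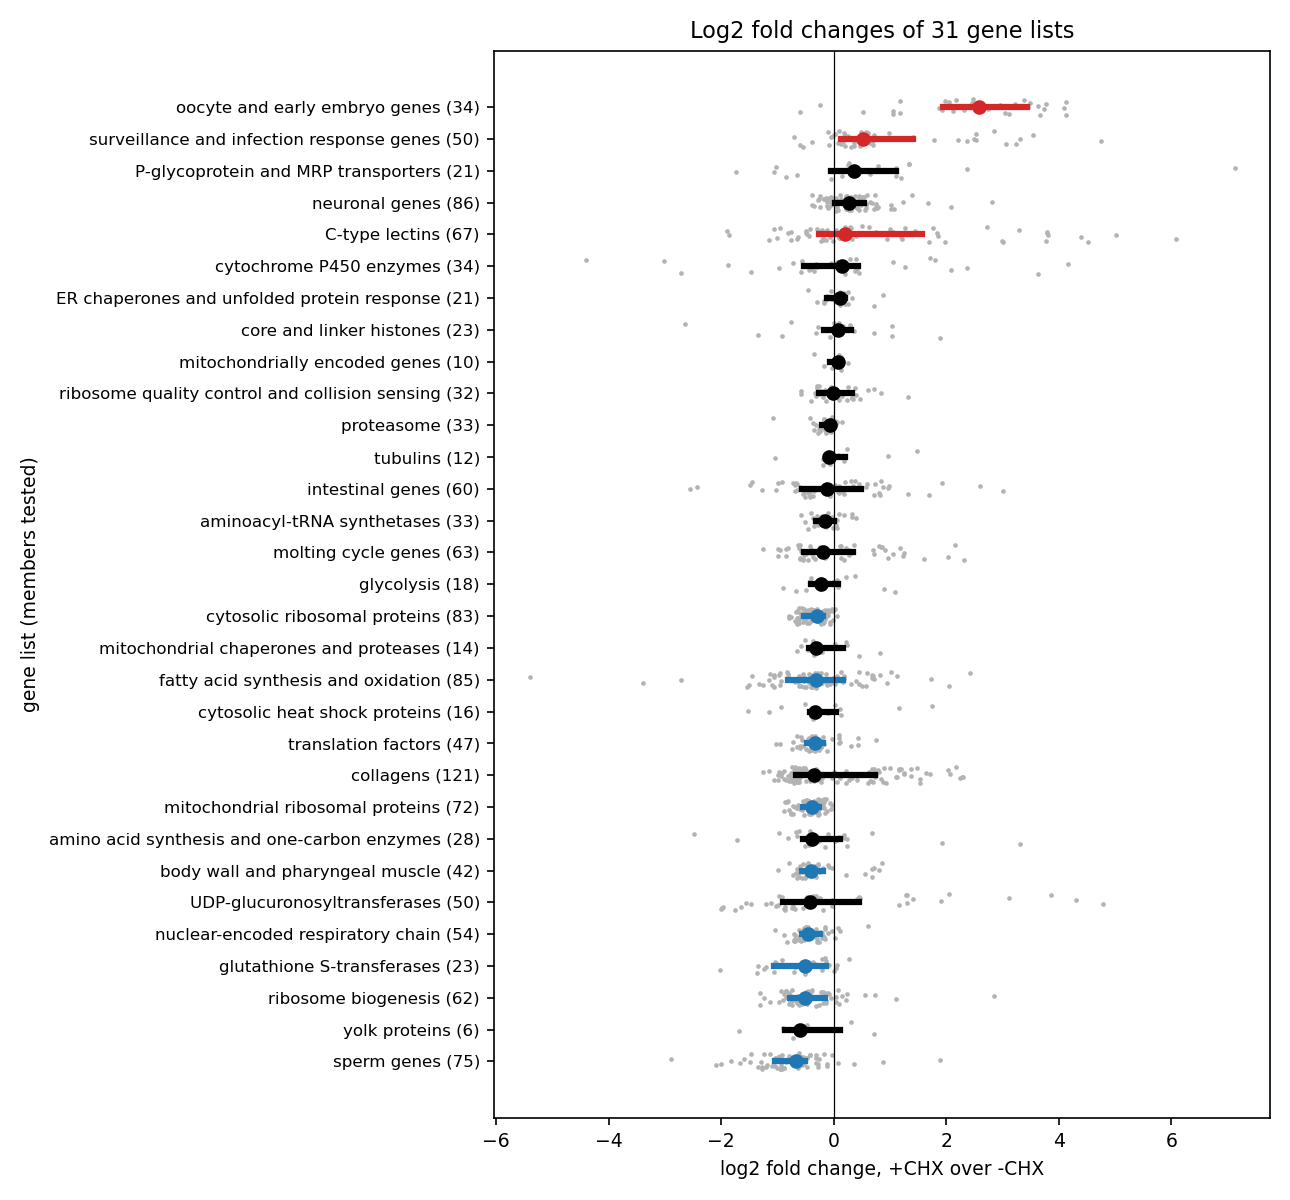
Log2 fold changes (CHX-treated over untreated) of 31 gene lists, with a grey point per tested member, a dot at the list median and a bar from the lower to the upper quartile, red or blue where camera passed at its preset correlation. Medians run from -0.67 (sperm genes) to 2.59 (oocyte and early embryo genes), and 0 lists passed with an estimated correlation.

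Nuclear genes of the respiratory chain fell, and the mitochondrially encoded genes did not pass in either direction. Of 54 nuclear genes 39 fell (41 adjusted over the list alone) and none rose, including the ATP synthase genes atp-2 (2578 ± 89.7 to 1594 ± 76.3 CPM, log2 fold change -0.69 ± 0.09) and asb-2 (-0.82 ± 0.10) and the complex III gene ucr-2.2 (-0.88 ± 0.12). Over the whole list the median was -0.45 (camera adjusted p = 5.6e-08; adjusted p = 0.363 with an estimated correlation). Of 10 mitochondrially encoded genes none passed, over all genes or the list alone (median 0.08, camera direction down, adjusted p = 0.810), and the 2 with the smallest p were nduo-2 (0.26 ± 0.28) and nduo-3 (-0.34 ± 0.27). Their counts were few: 0.0314% ± 0.00499 of the total without and 0.0336% ± 0.0110 with CHX (exact permutation p = 0.70). Of 14 mitochondrial chaperone and protease genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with the chaperonin gene hsp-60 at -0.65 ± 0.09 and the mitochondrial DNA-binding gene hmg-5 at 0.83 ± 0.13 (median -0.32, camera adjusted p = 0.196). The mitochondrial stress marker hsp-6 was at -0.21 ± 0.09 (edgeR adjusted p = 0.066), and passed with DESeq2 size factors (0.045), with upper-quartile factors (0.028), and without untreated replicate 2 (0.0494) or 3 (0.0499).

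Fatty acid synthesis and oxidation genes fell more often than they rose, 38 against 14 of 85 (41 and 15 adjusted over the list alone). The acyl-CoA dehydrogenase gene acdh-1 (WBGene00016943, chromosome I, 6497436 to 6499560) had a log2 fold change of -1.45 ± 0.11, and the enoyl-CoA hydratase gene ech-6 went from 1338 ± 32.1 to 638 ± 30.4 CPM (-1.07 ± 0.09). For acdh-2 there were 137 counts without and 3 with CHX, a ratio of 47.4 with an interval of 15.9 to 233 (counting error only). Leaving out 1 library at a time gave fitted log2 fold changes of -6.30 to -4.86 for acdh-2. The acyl-CoA synthetase gene acs-17 rose by 1.13 ± 0.11. The list median was -0.32 (camera adjusted p = 0.0022; adjusted p = 0.363 with an estimated correlation), and the call ended with a filter of 50 counts (adjusted p = 0.086). Of 18 glycolysis genes 3 rose and 7 fell (3 and 9 adjusted over the list alone), with gpd-1 at 1.09 ± 0.19 and gpd-2 at -0.67 ± 0.11 (median -0.22, camera adjusted p = 0.326). Of 28 amino acid synthesis and one-carbon genes 3 rose and 13 fell (3 and 14 adjusted over the list alone). The glutamine synthetase genes gln-5 and gln-6 rose by 3.32 ± 0.30 and 1.93 ± 0.17, against a list median of -0.39 (camera adjusted p = 0.113). The homologue of ATF4, listed as atf-5, had too few counts to test (1, 2 and 5 without, 2, 4 and 1 with CHX).

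Calls of several stress genes changed when 1 untreated library was left out. Of 16 cytosolic heat shock genes 9 fell and 2 rose, over all genes and the list alone. The small heat shock genes sip-1, known from oocytes and embryos, and hsp-43 rose by 1.75 ± 0.10 and 1.16 ± 0.16. In untreated replicate 3, 14 of the 16 genes lay above the mean of the other untreated libraries, and hsp-16.2 had 925 counts against 175 and 297. The median log2 ratio there was 0.43 for the heat shock genes and 0.15 for the ER chaperone genes. All other genes had a median absolute log2 ratio of 0.21. The heat shock list did not pass (median -0.33, camera adjusted p = 0.721), and its median ran from -0.48 to -0.21 when 1 library was left out. The call of hsp-16.2 (-1.14 ± 0.40, edgeR adjusted p = 0.035) ended without untreated replicate 3 (log2 fold change -0.26, adjusted p = 0.23). It also ended without any single CHX library (0.063 to 0.099), with a filter of 50 counts (0.0631) and with DESeq2 (0.18). The abundant chaperone genes hsp-1 (-0.33 ± 0.12, edgeR adjusted p = 0.043) and hsp-90 (-0.37 ± 0.12, 0.027) lost their calls without untreated replicate 3 (log2 fold changes -0.21 and -0.25) and without any single CHX library (adjusted p = 0.052 to 0.090). They also lost them with the filter of 50 counts (adjusted p = 0.0960 and 0.0638). Of 21 ER chaperone and unfolded protein response genes 3 rose and 2 fell (2 and 1 adjusted over the list alone), with pek-1, the PERK gene, at 0.89 ± 0.22 and manf-1 at -0.45 ± 0.11 (median 0.11, camera adjusted p = 0.793). The BiP gene hsp-4 was at -0.05 ± 0.32 and xbp-1 at 0.11 ± 0.15 (edgeR adjusted p = 0.92 and 0.60). Without untreated replicate 3 both rose, by 0.62 ± 0.15 and 0.33 on the log2 scale (edgeR adjusted p = 0.0059 and 0.019).

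**Figure D4:**
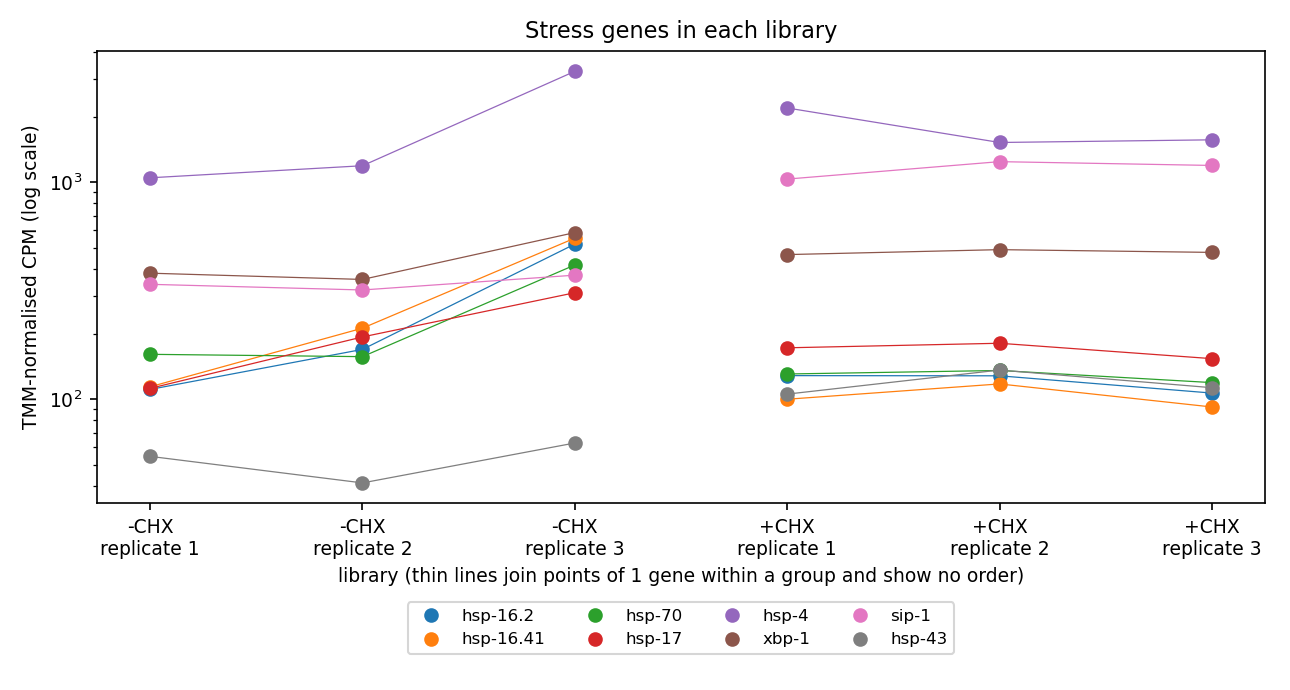
TMM-normalised CPM (log scale) of 8 stress genes in each of the 6 libraries, with thin lines joining the points of a gene within a group. Untreated replicate 3 lies above the other untreated libraries, at 519 CPM for hsp-16.2 against 111 and 170 CPM, while sip-1 and hsp-43 are higher in all CHX libraries.

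Genes of the cuticle moved in both directions. Of 121 collagens 37 rose and 53 fell (42 and 54 adjusted over the list alone), with col-98 rising from 57.7 ± 22.2 to 283 ± 71.9 CPM and col-80 from 379 ± 97.6 to 1091 ± 174 CPM. The collagen median was -0.35 and the mean 0.05 (camera direction down, adjusted p = 0.113). Of 63 molting cycle genes 12 rose and 18 fell, over all genes and the list alone, with the hedgehog-related gene wrt-4 at -1.26 ± 0.19 and ptr-24 at -0.95 ± 0.10 (median -0.19, mean 0.03, camera direction down, adjusted p = 0.260). Both lists passed without CHX replicate 1 (medians -0.36 and -0.29, camera adjusted p = 0.026 and 0.036). Leaving out 1 library at a time gave molting medians of -0.29 to -0.11.

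Genes of body wall and pharyngeal muscle, pooled in a single list, fell more often than they rose, 24 against 6 of 42 (27 and 7 adjusted over the list alone). The troponin I gene tni-1 went from 256 ± 6.84 to 128 ± 13.2 CPM. Log2 fold changes were -0.79 ± 0.09 for clik-1 and -0.73 ± 0.09 for the myosin light chain gene mlc-2, and the body wall myosin gene unc-54 was at -0.46 ± 0.09, while myo-5 rose by 0.86 ± 0.15. The median of the list was -0.40 (camera adjusted p = 1.1e-04; adjusted p = 0.330 with an estimated correlation). Of 86 neuronal genes 22 rose (17 adjusted over the list alone) and none fell, with the peptide genes nlp-28 and ins-7 at 2.81 ± 0.26 and 2.09 ± 0.27. The neuronal list did not pass (median 0.27, camera adjusted p = 0.076), but did without untreated replicate 1 (0.047). Of 60 intestinal genes 14 rose and 23 fell (15 and 24 adjusted over the list alone), with the cathepsin B gene cpr-1 at 1.69 ± 0.17 and the saposin-like gene spp-4 at -2.55 ± 0.25. The intestinal list did not pass (median -0.11, camera adjusted p = 0.260), but did without untreated replicate 3 (median -0.21, 0.042), and its median was 0.03 with no count filter.

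Of 12 tubulin genes 2 rose and 1 fell, over all genes and the list alone, with tbb-6 at 1.48 ± 0.30 and tba-4 at -1.05 ± 0.10 (median -0.09, mean 0.09, camera direction down, adjusted p = 0.726). Of 80 histone genes 40 had no count and 23 were tested, of which 4 rose and 4 fell, over all genes and the list alone. The linker histone gene hil-5 was at -1.35 ± 0.13 and his-70 at -2.64 ± 0.35 (median 0.08, camera direction down, adjusted p = 0.721), and copies of histone genes share sequence. Of 6 yolk genes vit-2 rose (2824 ± 435 to 4643 ± 1465 CPM, log2 fold change 0.72 ± 0.18) and vit-3 fell (-1.68 ± 0.46), over all genes and the list alone, although the vit-3 call was lost with DESeq2 (adjusted p = 0.12). Leaving out 1 library at a time gave 0.43 to 0.86 for vit-2 and -2.92 to -1.22 for vit-3. Yolk genes held 1.70% of counts in CHX replicate 2 and 0.859% and 0.883% in the other CHX libraries. The yolk list did not pass (median -0.60, camera adjusted p = 0.529), and without that library its median was -1.37 (adjusted p = 2.3e-04).

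The genes with the highest counts were much the same in both groups: eef-1A.1, unc-54, hsp-1 and vit-6 were among the 5 highest in each, with hsp-90 also among them without and vit-2 with CHX. The highest, eef-1A.1, went from 9135 ± 482 to 6709 ± 301 CPM and unc-54 from 6328 ± 347 to 4596 ± 325 CPM, while vit-6 (4709 ± 687 and 5815 ± 2683 CPM) did not pass (edgeR adjusted p = 0.31). The 10 genes with most counts held 4.57% ± 0.197 without and 4.25% ± 0.367 with CHX (exact permutation p = 0.30), and the 100 with most counts 19.2% ± 0.496 and 17.6% ± 0.146 (p = 0.10). Collagens held 5.97% ± 0.177 and 5.72% ± 0.0944 (p = 0.10) and yolk genes 0.875% ± 0.128 and 1.15% ± 0.480 (exact permutation p = 0.50). The transcription factor genes daf-16 (0.12 ± 0.11) and skn-1 (-0.02 ± 0.11) did not pass (edgeR adjusted p = 0.42 and 0.93). In all, 12 of the 31 lists passed camera at its preset correlation, 3 higher and 9 lower, and 0 passed with an estimated correlation (lowest adjusted p = 0.107).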

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

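With DESeq2, 1654 genes were higher and 1689 lower with CHX. With a filter of 50 counts in 3 libraries, 492 and 181 genes were at least 2-fold higher and lower, since 5993 genes were then tested. Leaving out each library in turn gave 1876 to 2155 higher and 1763 to 2173 lower genes, and 12 to 15 lists. With an estimated inter-gene correlation 0 lists passed and with fry 18 did, among them the synthetase, P-glycoprotein, mitochondrial chaperone, one-carbon, collagen and neuronal lists. With the replicate block, 2084 genes were higher and 1839 lower, and 3892 of the 4492 calls were kept. Under that block hsp-1, hsp-90, hsp-16.2 and gcn-1 did not pass (edgeR adjusted p = 0.104, 0.0736, 0.103 and 0.0777) and the neuronal list did (camera adjusted p = 0.0497). Libraries with the same number did not deviate together (r = -0.11, -0.08 and -0.08), so no pairing by number was seen in the counts. Shared growth or preparation of such libraries is not excluded. The list medians and named genes that changed sign under an alternative are those given next, and none had passed the threshold. The intestinal median was 0.0328 with no count filter, C52E12.1 and skn-1 were at 0.0143 and 0.0322 with the strict filter, and hsp-4 at 0.13 with the replicate block. Without single libraries, medians ran from -0.00944 to 0.27 for cytochrome P450, -0.0601 to 0.16 for ER chaperones and -0.10 to 0.28 for mitochondrially encoded genes, and genes from -0.37 to 0.62 for hsp-4, -0.0761 to 0.33 for xbp-1, -0.13 to 0.0120 for skn-1 and -0.14 to 0.50 for vit-6. Likewise the difference in share of counts, in percentage points, ran from -0.00229 to 0.00837 for mitochondrially encoded genes and -0.00383 to 0.418 for yolk genes. The cause was not tested. Every gene of the table was protein-coding, so the protein-coding alternatives changed nothing and have no values, and those on coding length were not run. What can be said of small changes and of genes with few counts is limited, and whether depth sets that limit was not tested.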

Other observations

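Families of genes defined by symbol prefix (85 families), and the members named in this paragraph and the next, were chosen after their values were seen. Transthyretin-related genes of the ttr family, secreted proteins for the most part, rose in 26 of 47 cases and fell in 6, with ttr-51 at 1.47 ± 0.09, ttr-15 at 1.49 ± 0.12 and ttr-26 at 2.10 ± 0.18 (family median 0.62, camera adjusted p = 1.5e-04; adjusted p = 0.626 with an estimated correlation). Among the pals genes, known from the intracellular pathogen response, 6 of 11 rose and none fell, with pals-32 at 3.54 ± 0.28 and pals-14 at 3.32 ± 0.32 (median 0.72, camera adjusted p = 2.3e-04; adjusted p = 0.626 with an estimated correlation). The Skp1-related genes of the skr family rose in 7 of 13 cases, among them skr-7 at 3.58 ± 0.41 (camera adjusted p = 0.059). Autophagy genes of the atg family rose in 6 of 10 cases (atg-13 at 0.88 ± 0.15, camera adjusted p = 0.178) and genes of the ced family, among them the caspase gene ced-3 at 1.31 ± 0.16 and the engulfment receptor gene ced-1 at 0.87 ± 0.12, rose in 6 of 11 and fell in 1 (camera adjusted p = 0.175). The skr, atg and ced families did not pass, and some families that fell had lower adjusted p. Of 13 acdh genes 10 fell and none rose (camera adjusted p = 2.3e-04, and 0.626 with an estimated correlation).

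Muscle genes changed in both directions. Their list pools body wall and pharyngeal muscle, which were not tested apart, so its median need not describe either tissue. The 6 that rose were myo-5, the pharyngeal myosin genes myo-1 (0.68 ± 0.12) and myo-2 (0.56 ± 0.15), and the troponin genes tnc-2 (0.80 ± 0.16), tnt-4 (0.72 ± 0.13) and tni-4 (0.68 ± 0.13), while unc-54 of the body wall fell (-0.46 ± 0.09). Among oocyte genes, zif-1 was the member that did not pass (-0.24 ± 0.27, edgeR adjusted p = 0.51). Among sperm genes the transcription factor gene spe-44 had the lowest value seen, -2.90 ± 0.44.

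The tests on scaling, on the share of germline tissue, on a mix-up of libraries and on a shift of a whole library were set after the results were seen, and the others before. Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many changed genes as the treatment (4492), which was the treatment itself, and the highest other gave 0. For lists, 7 of the splits gave as many as the treatment (12), and the highest other gave 17. With 10 splits a share under 0.05 cannot be reached. Each other split mixed treated and untreated libraries, so the treatment difference widened the spread within groups and partly remained between them. Neither the 0 genes nor the lists of those splits therefore measure what chance gives.

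Oocyte genes higher and sperm genes lower may reflect a later point in germline development of the CHX animals, a larger share of germline tissue, or scaling. Scaling moves all genes of a library alike and was argued against as the cause of the whole pattern, since the bootstrap intervals of the oocyte (2.12 to 3.11) and sperm (-0.91 to -0.62) medians lay 2.74 apart. A larger germline share was argued against as the cause of the oocyte rise, since germline genes outside gametes had a median of 0.10 (-0.13 to 0.20; 15 of 56 rose and 9 fell). A later stage stayed open: the adult collagen gene col-19 rose by 0.70 ± 0.14 (edgeR adjusted p = 0.0015), short of the 2-fold set beforehand, and of the yolk genes vit-2 rose (0.72), vit-3 fell (-1.68), and vit-6, vit-1, vit-4 and vit-5 were at 0.30, -0.72, -0.91 and -0.47 without passing. RNA-seq of the same animals and animals staged by gonad and vulva would separate stage from translation.

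Lower counts of ribosomal protein genes could come from a general compression of abundant genes, from dilution by transcripts that rose, or from lower synthesis of ribosomal proteins. Compression stayed open, because the list median lay at percentile 22.75 of random lists matched on mean count, and the top decile of genes by mean CPM had a median of -0.23. The list median was -0.23 without the genes at least 2-fold higher, against -0.30 with all genes. That comparison decided nothing on dilution, because TMM scaling offsets a fall shared by most genes before either median is taken. Genes that rose by less than 2-fold also stayed in. Dilution stayed open as the cause of all or a part of the fall. Ribosome biogenesis genes lay below all matched random lists (percentile 0.00), as did mitochondrial ribosomal proteins, the nuclear-encoded respiratory chain and sperm genes. Collagens and UDP-glucuronosyltransferases, which did not pass camera, did so too. Among the lists that passed as higher, oocyte and surveillance genes lay at percentile 100 and C-type lectins at 95.7. Matched lists had low medians for other lists of abundant genes too. These were -0.17 for translation factors, -0.20 for muscle, -0.21 for cytosolic heat shock proteins and -0.21 for the proteasome. Those lists lay at percentiles 2.21, 0.37, 19.4 and 90.76, so the proteasome median was above most matched medians.

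High heat shock counts in untreated replicate 3 stood beside other high genes. Of the 30 genes highest there against the other untreated libraries, 2 were heat shock genes. Log2 ratios of cnc-2, ptr-22, hsp-4 and nlp-31 (all but hsp-4 chosen after their values were seen) were 3.49, 2.87, 1.54 and 1.44, against 1.91 for hsp-16.2. Counts in the other untreated libraries were few for cnc-2 (1 and 11) and ptr-22 (6 and 6). Other libraries were not ranked in this way, so a departure particular to this library was not shown. The high heat shock counts may come from a stress of that culture or its handling, a mix-up of libraries, or a shift of the whole library. A mix-up between the groups was argued against: the lowest r with its own group exceeded the highest with the CHX group by 0.0713. The test of a whole-library shift (0.0299) decided nothing, because TMM scaling sets the median of all other genes near 0. Stress of that culture was not tested.

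X-linked genes had a median of 0.06 (camera adjusted p = 0.945, and 0.932 without the oocyte list).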
